A study of Mus musculus with 17 samples.

How the data were processed

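Adult mouse DRG and cultures of embryonic mouse DRG were profiled by RNA sequencing. The labels' protocols describe Nanopore sequencing of PCR-amplified cDNA from 50 ng of RNA for the RiboTag libraries, and give no separate protocol for bulk and IP libraries. Reads were mapped with minimap2, handled with SAMtools and compared with edgeR on the GRCm38.p6 genome build, per the submitters' processing notes. The versions of these tools, the use of strand and the counting of reads on genes are not given in the sources used here. The labels give 17 samples: bulk DRG (uninjured 3, injured 3), RiboTag DRG (uninjured 3, injured 3), IgG IP (1), CSDE1 IP of control cultures (2) and CSDE1 IP of cultures with 5'UTRm (2). Cultures were from embryonic day 13.5 and taken on day 5 in vitro, and lentivirus, where used, was added on day 2 in vitro. The labels give C57/BL6 for bulk mice, but the series' design text names CD-1 mice. Comparisons of RiboTag with bulk set different mouse lines against each other, whichever of these applies.

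The deposited tables hold a score for each feature and sample, which the authors scaled to a fixed library total and rounded to whole numbers (CPM). No header states this unit; it was read from the values, which step by a constant in each library and match the deposited log2 mean CPM. The signal values of RiboTag libraries, from which whole reads can be recovered in all 6, were scaled and rounded by the authors in the same way. The log2 fold changes, and the likelihood ratio score beside them, were computed by the authors with edgeR, per the file headers. The p-value and false discovery rate columns were computed by the authors with edgeR's likelihood ratio test, as their headers show. The authors kept features with a bulk p under 0.05 and at least 1 RiboTag read (1403 features of 56305 tested), and transcripts with a CSDE1 p under 0.01 (530 of 59188 tested); both selections were read from the values. By rank, 26 of 162 bulk features and 30 of 46 RiboTag features with a false discovery rate under 0.05 are not in the adult table. Headers use single letters: u in the adult table is uninjured per the labels, and c was read as injured. In the CSDE1 table c was read as control and u as 5'UTRm. No column belongs to the IgG IP, and a comparison of CSDE1 with IgG was not analysed here.

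Coordinates and gene types came from GENCODE M21 (GRCm38), which holds 1382 of the adult features (1381 protein coding) and 527 of the CSDE1 transcripts. Transcript length was that of the longest protein-coding transcript of a gene. In all 20 features that share a symbol with another were removed, which left 1383 genes. Effective reads were taken from the step between CPM values, wherever 1 read was worth more than 1 CPM, and whole reads were recovered from them for the RiboTag libraries. At least 99.5% of the values fell on whole reads there. The value of 1 read was 3.35, 19.3 and 6.82 CPM in the uninjured and 33.3, 8.88 and 12.6 CPM in the injured RiboTag libraries. A floor is the CPM of 3 reads, the upper 95% limit that a count of 0 allows.

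The design, written before the data were examined, planned edgeR for read counts and limma for normalized values. Because the tables hold rounded CPM, groups were compared with limma (empirical Bayes with a trend) on log2(CPM + 1), for genes with at least 1 CPM in as many libraries as the smallest group has. Bulk comparisons and the difference of injury effects were adjusted (Benjamini and Hochberg) over the 56305 features the authors tested, and CSDE1 over 59188, which treats every feature absent from the table as having a larger p. RiboTag and RiboTag against bulk were adjusted over the table's genes, since selection was on bulk p. These numbers of tests were chosen after the data were seen. The threshold was an adjusted p under 0.05. As an alternative chosen after the data were seen, edgeR's quasi-likelihood test was run on recovered RiboTag reads (minimum count 10). The authors' own statistics are printed as such beside these.

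Replicates were checked against sampling noise. Bulk uninjured replicates 1 and 2 varied 0.37 times as much as the noise and were averaged into 1 sample, a choice made after the data were seen. RiboTag injured pairs varied 0.77, 1.05 and 1.44 times as much as noise. Replicates of the same number were not treated as pairs, because their correlations across genes were 0.36, -0.05 and 0.13 in bulk, -0.03, -0.03 and 0.14 in RiboTag and -0.21 and -0.21 in CSDE1 libraries, and not all were above 0.1. Leaving out a library so that 1 sample remained in a group assumed that the lone sample varies like the others.

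Named genes followed a rule written before the data were examined: a panel of 20 genes for DRG injury, of which 9 were in the table; up to 8 genes per direction with the largest change among those past the threshold whose libraries did not overlap; 3 members of each list by p; and, where none passed, 3 genes per direction by p. The panel genes Csde1, Npy, Calca, Scn10a, Tubb3, Avil, Rpl22, Plp1, Mpz, Apoe and Cd74 were not in the adult table, and none of the 10 CSDE1 panel genes was in the CSDE1 table. Other genes named from the authors' deposited table or as examples were chosen after their values were seen.

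In all, 22 lists written before the data were examined were tested with camera (inter-gene correlation preset at 0.01) if at least 4 members were measured, with estimated correlation and fry as alternatives. In bulk 11 lists, in RiboTag 8, in the difference of injury effects 11 and in RiboTag against bulk 11 qualified. Lists with fewer members were ion channels of excitability, pan-neuronal genes, Schwann and satellite glia genes, immediate-early genes, RNA-binding protein genes, cell cycle genes and cytosolic ribosomal protein genes. In RiboTag the injury-induced neuropeptide, immune cell, and fibroblast and vascular lists also had too few, with 3 members each. Large-fibre sensory neuron, synaptic vesicle, blood cell and mitochondrially encoded genes had 0 members in the table.

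Each test was run on simulated data with known changes, adjusted over the simulated genes alone. The simulation used the same dispersion for every gene and library, and assumed a depth for bulk libraries whose depth could not be read. It drew bulk uninjured replicates 1 and 2 independently before they were averaged, although the real ones varied less than noise. The rates below hold for these settings. For bulk, the difference of injury effects and CSDE1 the adjustment over simulated genes is more lenient than the reported one over all features. Recovery by those reported tests would be no higher than the rates below. On the real bulk values the lenient adjustment called 102 genes in place of 4. Of genes with a log2 change of 2, bulk limma recovered 53.7%, RiboTag limma 6.1%, the difference of injury effects 1.5%, RiboTag against bulk 13.4% and CSDE1 0.0%. The test on reads recovered 80.0% of only 5 such genes, among the 60 genes with enough reads, where the limma rates rest on 33 to 67 genes. False calls made up 0.0% in bulk and RiboTag limma, 6.2% on reads, 8.3% in the difference of effects and 10.3% in RiboTag against bulk. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.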

Results

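The series measured RNA of mouse dorsal root ganglia (DRG), the ganglia that hold the cell bodies of sensory neurons, by RNA sequencing (Nanopore sequencing of PCR-amplified cDNA, in a shared protocol that names ribosome-bound RNA). Its title places it in axon regeneration, around a non-coding role of Gpr151, a gene for an orphan G protein-coupled receptor. Whole lumbar DRG (levels 4 and 5) were taken from adult wild-type mice, uninjured (n = 3) or 24 h after sciatic nerve injury (n = 3), and are called bulk here. The same 2 conditions, with 3 samples each, were taken from RiboTag mice crossed with Advillin-Cre, in which the ribosomal protein Rpl22 carries an HA tag in sensory neurons, so that pulling down the tag enriches RNA on the ribosomes of those neurons. Cultured DRG neurons of embryonic day 13.5 were used for immunoprecipitation (IP) of the RNA-binding protein CSDE1, from control cultures (n = 2) and from cultures overexpressing a construct that the labels call 5'UTRm (n = 2). The 17th sample, an IP with control IgG (n = 1), was not analysed here. Values are reads scaled to a fixed library total (CPM) that the authors rounded to whole numbers, listed for features the authors selected: 1403 in the adult table and 530 transcripts in the CSDE1 table.

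Depth was read from the steps between the CPM values. The RiboTag libraries held about 298400, 51700 and 146600 reads when uninjured and 30100, 112600 and 79400 when injured, so that 3 reads, the limit a count of 0 allows, correspond to 10.1, 58.0, 20.5, 99.8, 26.6 and 37.8 CPM. Bulk uninjured replicates 1 and 2 held about 550800 and 918700 reads and bulk injured replicate 1 about 308100. In the other 3 bulk libraries 1 read was worth less than 1 CPM, and their depth could not be read. The CSDE1 IP libraries held about 126600 and 363700 reads in control cultures and 135900 and 190800 with 5'UTRm. Of the 1383 adult genes analysed, between 1148 and 1328 had a value above 0 in a bulk library, but 423 to 1138 in a RiboTag library. Bulk uninjured replicates 1 and 2 differed by less than the sampling noise (variance 0.37 times the noise over 704 genes, against 1.22 and 1.47 for the other uninjured pairs) and were counted as 1 sample, so bulk uninjured means have n = 2. Floors and intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. No label says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples.

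The first comparison asks which transcripts changed in whole DRG 24 h after the injury. Atf3, a stress-induced transcription factor of axotomized neurons, rose 57.1-fold, from 6.25 ± 1.06 CPM (SD, n = 2) to 357 ± 37.6 CPM (SD, n = 3). Gadd45a, a growth arrest and DNA damage response gene, rose 11.8-fold to 285 ± 59.6 CPM (SD, n = 3). The neuropeptide genes Adcyap1, which encodes PACAP, and Gal, which encodes galanin, rose 8.17-fold to 329 ± 54.4 CPM and 8.06-fold to 230 ± 69.1 CPM (SD, n = 3 each). In limma, with adjustment over the 56305 features that the authors tested, these 4 genes passed, with adjusted p of 4.7e-05 for Atf3, 0.0026 for Gadd45a and for Adcyap1, and 0.041 for Gal. The log2 difference was 5.63 for Atf3 (SE 0.18), 3.48 for Gadd45a (SE 0.20) and 2.92 for Gal (SE 0.26), and for each of the 4 genes all 3 injured libraries lay above all uninjured ones. Of 1349 genes tested, 554 had an unadjusted p under 0.05. The authors kept these genes on their bulk p in the same libraries, so that count was largely fixed in advance. limma's spread was estimated from these selected genes alone, which may make its p-values too small. No gene passed when uninjured replicates 1 and 2, uninjured replicate 3, injured replicate 1 or injured replicate 3 were left out, with 237, 381, 740 and 402 genes at an unadjusted p under 0.05, and 1 passed without injured replicate 2. In 1 fit with all adult libraries 0 passed, with 27 at an unadjusted p under 0.05. The authors' deposited table, from an edgeR likelihood ratio test, holds 135 genes with a false discovery rate under 0.05. It lists uninjured replicates 1 and 2 in separate columns, and may count as 2 samples what is counted as 1 here. Its bulk false discovery rates, here and below, may therefore be too small.

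Gpr151 lies on chromosome 18 at 42577881 to 42579652 on the minus strand in GRCm38 (GENCODE M21), a protein-coding gene with 1 exon. Its bulk values were 2, 2 and 1 CPM in uninjured DRG and 32, 28 and 13 CPM after injury, with means of 1.5 ± 0.707 CPM (SD, n = 2) and 24.3 ± 10 CPM (SD, n = 3). The values in uninjured replicates 1 and 2 lie under the floors of 5.4 and 3.3 CPM for 3 reads, so no fold is given. The difference was 3.28 on the log2(CPM + 1) scale (SE 0.56, 95% interval 2.00 to 4.55), with an adjusted p of 0.676 in limma. In the authors' deposited table Gpr151 is higher after injury with a false discovery rate of 1.9e-07, which may count uninjured replicates 1 and 2 as 2 samples. In RiboTag RNA, Gpr151 was listed at 0, 0 and 7 CPM in uninjured libraries and at 0 in all 3 injured ones, where the 3 libraries together give a floor of 13.5 CPM. The bulk injured mean of Gpr151 lies above that floor, while smaller values were not detectable at this depth.

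All 20 measured regeneration-associated genes were higher in bulk DRG after injury, 2 of them past the threshold over all features and 19 when adjusted over the list alone. Sprr1a, a small proline-rich protein induced in injured neurons, went from 1.75 ± 0.354 to 51 ± 20.1 CPM (SD, n = 2 and 3), Sox11, a transcription factor, from 3.5 ± 2.12 to 43.7 ± 13.1 CPM, and Jun from 48.5 ± 6.36 to 159 ± 68.2 CPM, none of these past limma's threshold. Gap43, a growth cone protein, went from 145 ± 6.72 to 217 ± 19.7 CPM. In the authors' deposited table, 19 of the 20 members have a false discovery rate under 0.05, among them Sprr1a (log2 4.96), Sema6a (log2 3.61), Sox11 (log2 3.52), Csf1 (log2 2.78) and Gap43 (log2 0.59). The list differed from the other genes by limma's camera (adjusted p = 1.5e-10), and not with an estimated correlation (adjusted p = 0.32 with an estimated correlation). The authors chose the genes of the table on their own bulk p under 0.05, so counts of members past a threshold in bulk are not independent evidence of direction. Measured members are only those that the table holds, here 20 of the 32 in the list. The directions of the other members are not known here. No member of these lists had another direction in bulk after quantile scaling, which moved the median difference of all tested genes from 0.47 to 0.20 on the log2 scale.

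All 4 measured injury-induced neuropeptide genes, Adcyap1, Gal, Nts (neurotensin) and Bdnf, were higher, 2 past the threshold and 4 when adjusted over the list alone (camera adjusted p = 0.00077, and 0.28 with an estimated correlation). Bdnf, a neurotrophin, had 21.8 ± 0.354 CPM uninjured and 54.3 ± 3.21 CPM injured (SD, n = 2 and 3). Genes of the ATF4 and unfolded protein response pathways were higher in 8 of 8 measured cases, of 24 in the list, none past the threshold and 6 when adjusted over the list alone (camera adjusted p = 0.0081, and 0.28 with an estimated correlation). In the authors' deposited table Chac1, a target of ATF4, has a log2 fold change of 2.18 and the endoplasmic reticulum chaperone Hspa5 of 0.55, each with a false discovery rate under 0.05. Axonal cytoskeleton genes were higher in 7 of 7 measured cases, of 40 in the list, none past the threshold and 5 when adjusted over the list alone (camera adjusted p = 0.012, and 0.40 with an estimated correlation). Tubb2b, a neuronal beta-tubulin, had 401 ± 18.4 CPM uninjured and 565 ± 52.3 CPM injured (SD, n = 2 and 3), and Stmn4, a stathmin that binds tubulin, 12 ± 8.49 and 58 ± 28.8 CPM.

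All 5 measured nociceptor genes, of 26 in the list, had lower means after injury, none past the threshold and 4 when adjusted over the list alone (camera adjusted p = 0.0092, and 0.32 with an estimated correlation). Scn11a, the sodium channel Nav1.9, had 150 ± 2.12 CPM uninjured and 114 ± 2.89 CPM injured (SD, n = 2 and 3), Cd55, a complement inhibitor, 194 ± 4.95 and 128 ± 24.2 CPM, and Tac1, the substance P precursor, 274 ± 20.9 and 202 ± 28.9 CPM. The 4 measured nuclear genes of oxidative phosphorylation were also all lower (camera adjusted p = 0.031, and 0.39 with an estimated correlation), none of them when adjusted over the list alone. Ndufa4, a subunit associated with cytochrome oxidase, had 857 ± 37.1 CPM uninjured and 705 ± 78.1 CPM injured. Immune cell genes were higher in 4 of 4 cases without passing camera (adjusted p = 0.147), and 1 member, the macrophage lectin Lgals3, passed when adjusted over the list alone (37.8 ± 4.60 to 92.7 ± 15 CPM). Lists whose 4 or more members did not pass camera were fibroblast and vascular genes (3 higher and 1 lower, adjusted p = 0.38), translation factors (8 higher and 1 lower, 0.206), cholesterol synthesis genes (3 and 1, 0.585) and published CSDE1-associated mRNAs (2 and 2, 0.594).

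Among single genes in the authors' deposited table, 119 of the 135 with a false discovery rate under 0.05 are higher after injury and 16 are lower. Among the largest increases in the authors' deposited table are Cckbr, a cholecystokinin receptor (log2 6.52), Atf3 (log2 5.82), Flrt3, a fibronectin leucine-rich transmembrane protein (log2 5.12), Serpine1, an inhibitor of plasminogen activators (log2 4.94), Fgf3 (log2 4.20) and Plaur, the urokinase receptor (log2 4.02). Cckbr was listed at 0 in the uninjured libraries and at 13, 13 and 9 CPM in the injured ones. Among the largest decreases in the authors' deposited table are Pygm, muscle glycogen phosphorylase (log2 -5.15), Cntn6, a contactin (log2 -3.05), the collagen gene Col9a2 (log2 -3.02), Ift122, of intraflagellar transport (log2 -1.52) and Mrgpra2b, a receptor of pruriceptive neurons (log2 -1.17). Lrrn1, a leucine-rich repeat protein that also has a false discovery rate under 0.05 there, went from 154 ± 4.24 to 78.3 ± 22.1 CPM (SD, n = 2 and 3). Pygm had 4 CPM in each uninjured library and was listed at 0 in each injured one.

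**Figure D1:**
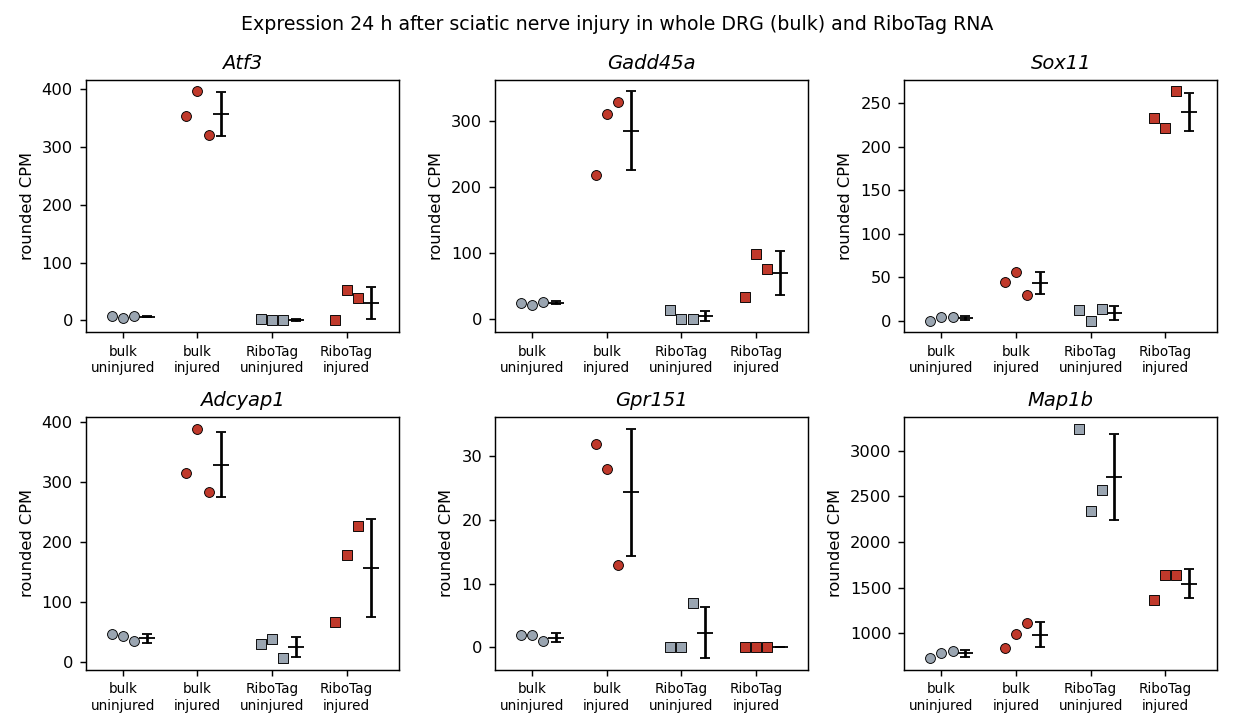
Rounded CPM of Atf3, Gadd45a, Sox11, Adcyap1, Gpr151 and Map1b in each of the 12 adult libraries (points), by group, with the mean and SD beside them (bars; n = 3, and n = 2 for bulk uninjured, where replicates 1 and 2 were counted as 1 sample). The axes are linear and differ between genes, and that of Map1b does not start at 0. Sox11 lies at 233, 222 and 264 CPM in injured RiboTag libraries against 13, 0 and 14 CPM in uninjured ones, and Map1b at 1363, 1634 and 1637 against 3241, 2339 and 2565 CPM.

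The second comparison asks the same of ribosome-bound RNA of sensory neurons. In RiboTag RNA, Sox11 rose after injury, from 9 ± 7.81 to 240 ± 21.8 CPM (SD, n = 3 each). Its values in uninjured replicates 2 and 3 lie under the floors of 58.0 and 20.5 CPM for 3 reads, so no fold is given. Abi1, an adaptor of actin regulation, rose 6.28-fold to 266 ± 141 CPM, Rhoq, the small GTPase TC10, 4.29-fold from 40 ± 1.00 to 172 ± 25.4 CPM, and Cd44, a hyaluronan receptor, 2.48-fold to 476 ± 107 CPM. Rhoq overlaps the gene Pigf on the other strand, so part of its reads can belong to Pigf. In uninjured replicate 2 Rhoq also lies under the floor of 58.0 CPM, so its fold is uncertain. Dcaf10, a substrate receptor of a ubiquitin ligase, rose 1.43-fold from 4610 ± 580 to 6574 ± 315 CPM. Its level in RiboTag RNA lies far above that in bulk DRG, as given in the fourth comparison, and the origin of this signal was not tested. Map1b, a microtubule-associated protein of axons, fell to 0.569 times its level, from 2715 ± 469 to 1545 ± 157 CPM. These 6 of 850 genes passed limma with adjustment over the genes tested (adjusted p of 0.00064 for Map1b and for Dcaf10, 0.0091 for Sox11 and for Abi1, 0.021 for Cd44 and 0.047 for Rhoq), and 97 had an unadjusted p under 0.05. With adjustment over the features the authors tested, as for bulk, 2 passed, and without the 2 shallowest libraries (uninjured replicate 2 and injured replicate 1) 0 passed in limma, with 200 at an unadjusted p under 0.05 and 30 called on reads by edgeR. All 3 injured libraries lay on one side of the uninjured ones for each. Their log2 differences were 5.34 for Sox11 (SE 0.96), 2.50 for Abi1 (SE 0.45), 2.06 for Rhoq (SE 0.46), 1.32 for Cd44 (SE 0.27), 0.52 for Dcaf10 (SE 0.07) and -0.80 for Map1b (SE 0.11).

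The count for RiboTag depended on scaling and on single libraries. Quantile scaling gave 17 genes, 10 higher and 7 lower against 5 and 1, and moved the median from -0.27 to 0.15. It sets each value by its rank within a library. A gene of the same rank in every library then differs by 0, whatever its change in CPM. Map1b lay at 0.00 there, which does not test its fall. In 1 fit with all adult libraries there were 53, 22 higher and 31 lower. Without uninjured replicate 1 there was 1 gene, without uninjured replicate 2 there were 107 (8 higher and 99 lower), and without uninjured replicate 3, injured replicate 1 or injured replicate 2 there were 3. In the fit without uninjured replicate 2, both uninjured libraries left (298400 and 146600 reads) were deeper than every injured one (at most 112600 reads). Depth and injury cannot be told apart in that fit. On whole reads recovered from the CPM steps, edgeR's quasi-likelihood test called 20 of the 45 genes with enough reads, 14 higher and 6 lower. Among them were Sox11 (log2 4.20, adjusted p = 1.2e-07), Map1b (log2 -0.81, adjusted p = 0.00076), Tac1 (log2 -1.18, adjusted p = 0.010) and Kcnb2, a voltage-gated potassium channel (log2 -1.71, adjusted p = 0.0024). Kcnb2 had 126 ± 24.2 CPM in uninjured and 39.7 ± 9.07 CPM in injured RiboTag libraries (SD, n = 3 each).

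In the authors' deposited table, 16 genes have a false discovery rate under 0.05 in RiboTag RNA, 14 higher and 2 lower. Besides those above, the table lists as higher Adcyap1 (log2 2.83), Gal (log2 3.54), Gadd45a (log2 3.17), Sema6a, a semaphorin (log2 3.46), Wfdc3, of the WAP domain family (log2 5.47), Chst2, a sulfotransferase (log2 2.59), Klf6 (log2 1.20) and Syt4, a synaptotagmin (log2 0.90), and as lower Slc17a6, the vesicular glutamate transporter VGLUT2 (log2 -2.31). Adcyap1 had 25.3 ± 16.5 CPM uninjured and 157 ± 82.0 CPM injured (SD, n = 3 each), and Gadd45a 4.33 ± 7.51 and 69 ± 33.1 CPM. Rhoq and Pigf overlap at their ends on opposite strands of chromosome 17 (86963082 to 87000069 and 86997256 to 87025406), and both have higher values after injury. Reads in the overlap cannot be assigned to 1 of them, because the use of strand is not given in the sources used here. Of 16 measured regeneration-associated genes 15 were higher in RiboTag RNA, 2 past the threshold and 5 when adjusted over the list alone. The list passed camera (adjusted p = 4.7e-09), but not with an estimated correlation (adjusted p = 0.118 with an estimated correlation) or in fry (adjusted p = 0.092). The other 7 lists with enough members did not pass camera, with adjusted p between 0.593 and 0.742. They were the nociceptor (0 of 4 higher), cholesterol synthesis (2 of 4), ATF4 and unfolded protein response (1 of 5), axonal cytoskeleton (5 of 6), CSDE1-associated (2 of 4), oxidative phosphorylation (1 of 4) and translation factor lists (3 of 7).

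Bulk and RiboTag changes overlapped in the authors' deposited table. There 11 genes have a false discovery rate under 0.05 in both, all 11 with the same sign, where 1.56 would be shared by chance (Fisher's exact test, two-sided, p = 1.5e-08). These genes were in the table because of their bulk p, and 30 of the 46 RiboTag features with a false discovery rate under 0.05 are not in it, so this overlap holds only within the table. The 1.56 also treats every gene as equally able to be called in RiboTag RNA, but only 503 have at least 10 RiboTag reads in all. It may be too low, and the Fisher p-value is descriptive only. Of the 4 and 6 genes that passed limma none was shared, with 0.0283 expected (Fisher's exact p = 1). In the authors' deposited table, 56 genes are higher in bulk with a false discovery rate under 0.05 and have at least 10 RiboTag reads in all. Of these, 51 have a higher RiboTag value after injury. Of the 9 genes that are lower in bulk by the same rules, 7 have a lower RiboTag value. Across 848 genes tested in both, the limma differences correlated with a Pearson r of 0.30 and a Spearman rho of 0.26, with 60.3% of signs shared. Among 89 genes with a mean of at least 50 CPM in both kinds of library, rho was 0.52. Genes are not independent replicates, so no p is given for these correlations.

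**Figure D2:**
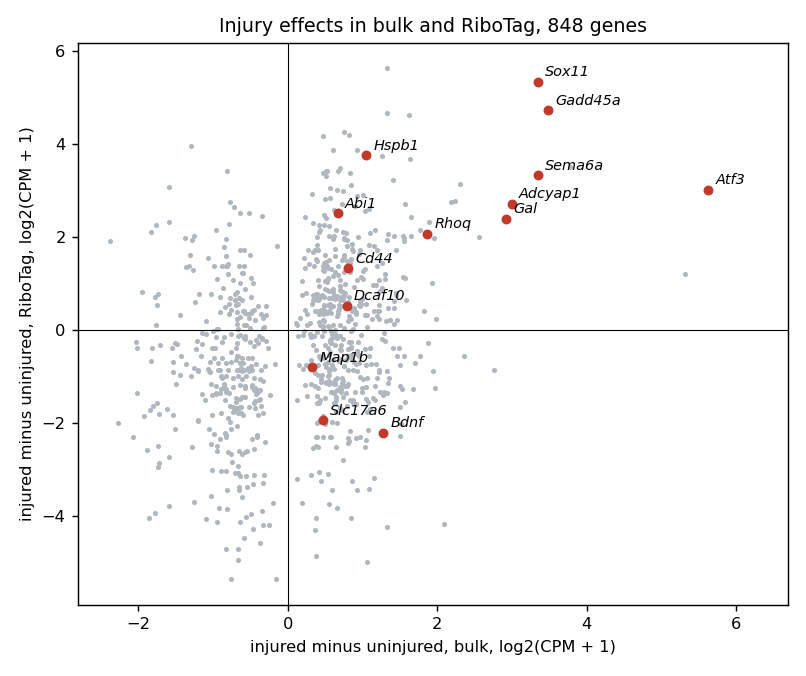
Difference between injured and uninjured libraries on the log2(CPM + 1) scale in bulk (x axis) and RiboTag RNA (y axis) for 848 genes (points), with 14 named genes in red. Sox11 lies at 3.35 and 5.34, Atf3 at 5.63 and 3.01, and Map1b at 0.32 and -0.80.

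The third comparison asks whether the injury effect itself differed between ribosome-bound and total RNA. Map1b, on chromosome 13 at 99421446 to 99516540 on the minus strand (GRCm38, GENCODE M21), had the smallest p: it lay at 781 ± 35.0 and 985 ± 136 CPM in bulk (SD, n = 2 and 3) and at 2715 and 1545 CPM in RiboTag RNA. The RiboTag effect minus the bulk effect was -1.13 on the log2 scale (SE 0.16, 95% interval -1.47 to -0.79, adjusted p = 0.101 in limma). Zfp804b, a zinc finger gene, had 813 ± 1.06 and 727 ± 30.7 CPM in bulk and 40, 77 and 20 CPM against 0 in all 3 libraries in RiboTag RNA (-5.18, SE 0.84, adjusted p = 0.28). With a group at 0 that size is set by the pseudocount: for Zfp804b it was -8.47 with 0.1, -6.16 with 0.5 and -3.32 after quantile scaling. Napa, which encodes the vesicle fusion factor alpha-SNAP, had 17, 19 and 20 CPM against 0 in RiboTag RNA and 211 ± 33.6 and 272 ± 38.8 CPM in bulk (-4.65, SE 1.06, adjusted p = 1). In the other direction Cecr2, Col9a2 and Wfdc3 had the smallest p, with differences of 5.25, 5.28 and 4.29 and an adjusted p of 1 each, and as for Napa 1 group of libraries at 0. In limma, 0 of 1383 genes passed with adjustment over the 56305 features, 78 had an unadjusted p under 0.05, and no list passed camera (smallest adjusted p = 0.957). Map1b passed in limma without bulk injured replicate 1 (adjusted p = 0.0126) or bulk injured replicate 3 (0.036). Map1b and Zfp804b passed when adjusted over the genes of the table alone (0.0025 and 0.0070). Over its alternatives the adjusted p of Map1b ranged up to 1. Quantile scaling put the difference of Map1b at -0.16, but its RiboTag part was set by rank alone there.

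The fourth comparison asks which RNAs differ in level between RiboTag and bulk RNA of uninjured DRG. The 2 kinds of library differ in the pull-down, the mouse line and depth, whose effects cannot be told apart here. Uninjured RiboTag libraries held 51700 to 298400 reads, and bulk uninjured replicates 1 and 2 held 550800 and 918700. Genes entered the table on their bulk p and needed only 1 RiboTag read. That may favour lower RiboTag values in the counts and the median below. Dcaf10 was 527-fold higher in RiboTag RNA, at 4610 ± 580 CPM (SD, n = 3) against 8.75 ± 3.18 CPM (SD, n = 2). The other genes named here as higher differed far less. Whether this signal is Dcaf10 mRNA of the neurons was not tested. Pura, a single-stranded nucleic acid binding protein of neurons, was 11.3-fold higher, Slco1a6, an organic anion transporter, 11.1-fold, Golga4, a golgin, 9.98-fold and Map1b 3.48-fold. Lower values were found for Tuba1a, an alpha-tubulin of growing axons, at 208, 213 and 177 CPM against 4593, 4585 and 4506 CPM in bulk, for Hspb1, a small heat shock protein, at 3, 0 and 7 against 437, 484 and 467 CPM, and for Fabp7, a fatty acid binding protein of satellite glia, at 17, 0 and 20 against 585, 590 and 772 CPM. Slc1a1, a glutamate transporter, was listed at 0 in all 3 RiboTag libraries, whose pooled floor is 6.04 CPM, against 284 ± 13.4 CPM (SD, n = 2). In limma with adjustment over the table's genes, 194 of 1383 genes passed, 25 higher and 169 lower, with a median difference of -1.13 on the log2 scale. Quantile scaling gave 328, 167 higher and 161 lower, with a median of 0.26. Without bulk uninjured replicates 1 and 2 the count was 37, and without bulk uninjured replicate 3 it was 42.

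Fibroblast and vascular genes were lower in RiboTag RNA in 4 of 4 cases, all past the threshold and 4 when adjusted over the list alone (camera adjusted p = 4.4e-05, and 0.024 with an estimated correlation). Vim, vimentin, had 11 ± 6.93 CPM (SD, n = 3) against 399 ± 38.2 CPM (SD, n = 2), and the collagen gene Col3a1 3, 0 and 0 CPM against 160, 134 and 119 CPM. Oxidative phosphorylation genes were also lower in 4 of 4 cases, all past the threshold (camera adjusted p = 0.0018, and 0.045 with an estimated correlation), with Ndufa4 at 3, 19 and 7 against 870, 897 and 831 CPM. Axonal cytoskeleton genes were lower in 6 of 7 cases, 3 past the threshold, with Map1b the exception (camera adjusted p = 0.021, and 0.18 with an estimated correlation). Stmn2, a stathmin of neurons, had 182 ± 94.1 CPM against 1344 ± 4.24 CPM in bulk (SD, n = 3 and 2). Of the other lists, regeneration-associated genes (2 past the threshold higher and 3 lower, camera adjusted p = 0.927), neuropeptides (0.871), nociceptor genes (0.36), immune cell genes (0.78), cholesterol synthesis genes (0.36), ATF4 and unfolded protein response genes (0.105), CSDE1-associated mRNAs (0.105) and translation factors (0.871) did not pass. These lists were not matched for transcript length, and the median log2 ratio of RiboTag to bulk was -2.71 in the 169 shortest and -0.04 in the 169 longest of 845 genes. The directions of the fibroblast and vascular, oxidative phosphorylation and cytoskeleton members were the same after quantile scaling. Hspe1 and its near-identical copy Hspe1-rs1 were listed at 0 in all 3 uninjured RiboTag libraries and share reads, so their separate values are uncertain.

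The fifth comparison asks which transcripts were recovered more or less by CSDE1 IP in cultures overexpressing 5'UTRm. The labels list no input RNA of these cultures. Differences in binding cannot be told apart here from differences in transcript level or background. CSDE1 is a cold shock domain protein that binds mRNA. Which columns are control and which 5'UTRm was read from the initials of their headers, and the directions below rest on that. In the authors' deposited table, 248 transcripts of 240 genes are lower with 5'UTRm and 282 of 275 genes are higher, chosen on p under 0.01, with 0 genes in both lists. The transcript of Ebf1, a transcription factor, with the smallest p had 47 and 71 CPM in control IPs and 0 and 5 CPM with 5'UTRm, Prg4, a proteoglycan, 32 and 41 against 0 and 0 CPM, and the splicing factor Srsf7 16 and 16 against 0 and 0 CPM. Rhof, a Rho GTPase, had 16 and 19 CPM in control IPs and 81 and 89 CPM with 5'UTRm, and Dlx6, a homeobox gene, 16 and 16 against 81 and 68 CPM. None of the 530 has a false discovery rate under 0.05 in the authors' deposited table, where the smallest, for Ebf1, is 0.159. In limma 0 of 506 transcripts passed with adjustment over the 59188 transcripts the authors tested (smallest adjusted p = 0.0932), and 386 had an unadjusted p under 0.05. The transcripts were chosen on p in these same libraries, so that count was largely fixed in advance. The counts under the alternatives below share this limit. Quantile scaling gave 313 (155 higher and 158 lower, with the median moved from 1.48 to 1.20) and a pseudocount of 0.1 gave 72 (16 higher and 56 lower). Leaving out 1 library left 1 sample in a condition, so the spread came from the other condition alone. A transcript listed at 0 in both libraries of that other condition then has no spread of its own. The direction of calls in such fits was thus largely set by which library was left out, and their counts are not given.

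No list had the 4 members needed for a test in the CSDE1 table. Both measured members of the ion channel list were higher with 5'UTRm, the pacemaker channel Hcn2 at 16 and 16 against 66 and 52 CPM and the potassium channel subunit Kcnab2 at 0 and 0 against 29 and 5 CPM. Channel genes outside that list, chosen after their values were seen, lay in both directions, with Kcnn2 at 8 and 16 against 66 and 42 CPM, Trpc6 at 39 and 38 against 15 and 5 CPM and Ano4 at 39 and 30 against 7 and 0 CPM. Of pan-neuronal genes, Rbfox3 had 16 and 19 against 66 and 47 CPM and Map2 0 and 0 against 7 and 16 CPM. Of regeneration-associated genes, Fgf2 had 0 and 8 against 66 and 21 CPM and Cd44 0 and 0 against 7 and 16 CPM. Of oxidative phosphorylation genes, Ndufb2 had 39 and 55 against 7 and 10 CPM and Atp5g2 16 and 14 against 0 and 0 CPM. The macrophage receptor gene Csf1r had 47 and 36 against 7 and 10 CPM, and the glial gene Mag 24 and 11 against 0 and 0 CPM. The median transcript in the table had 9 reads over the 4 libraries, and 291 of the 530 were listed at 0 in both libraries of 1 condition.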

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

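Apart from the planned limma test of the difference of injury effects, the tests in this part were chosen only after the main results were seen, and what was expected was written before the values were computed only for the genes like Gpr151 and for length within neuron genes. Among the genes that the rule for named genes picked, Map1b, Bdnf, Cecr2 and Kcnh5 were marked because all their libraries separated in opposite directions in bulk and RiboTag RNA. The RiboTag effect minus the bulk effect was -1.13 on the log2 scale for Map1b, -3.48 for Bdnf, 5.25 for Cecr2 and -5.56 for Kcnh5, and none passed the test of that difference in limma (adjusted p = 0.101 for Map1b and 1 for the others). Bdnf had 20, 23 and 22 CPM in uninjured and 58, 52 and 53 CPM in injured bulk libraries, but 20, 58 and 20 CPM in uninjured and 0, 18 and 13 CPM in injured RiboTag libraries. Cecr2, a chromatin remodelling factor, went from 2, 2 and 1 CPM to 0 in bulk and from 0, 0 and 7 to 33, 62 and 13 CPM in RiboTag RNA. Kcnh5, a potassium channel, went from 0 to 3, 1 and 1 CPM in bulk and from 10, 39 and 14 CPM to 0 in RiboTag RNA. The bulk values of Cecr2 and Kcnh5 lie under the floors of the bulk libraries that have one (5.4, 3.3 and 9.7 CPM for 3 reads), so their separation in bulk is within what counts of 0 allow. In RiboTag RNA all values of Kcnh5, all but the 62 CPM of Cecr2 and all but the first of Bdnf lie at or under the floors of their libraries, so these separations rest on few reads. Among all genes, 19 separated in opposite directions and 83 in the same direction.

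Splitting the 6 RiboTag libraries into 3 and 3 in other ways gave as many genes as the 6 called by limma in 2 of 10 splits, counting the real one. The highest other count was 77, in the split that put the 3 deepest libraries against the 3 shallowest, which points to structure by depth. On recovered reads 1 of 10 splits, the real one with 20 genes, reached its count, and the highest other count was 0. With 10 splits no share can fall under 0.05.

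Gpr151 had no read in the injured RiboTag libraries. At its mean bulk level 5.40 reads were expected there, and the Poisson probability of 0 reads was 0.0045 (0.0416 at a level 1 SD lower). That counts PCR reads as independent molecules. The lowest bulk injured value lies under the pooled floor of 13.5 CPM. Depth alone was thus unlikely to account for the absence at the mean bulk level, but is not excluded. Of 76 genes of like length and bulk level, 13 also had none, or 17.1% (95% interval 9.43% to 27.5%), a low estimate because the table needs at least 1 RiboTag read, so low recovery could account for it. Of the 11 like genes that had risen in bulk, 0 had none. Weak loading of Gpr151 mRNA on ribosomes remains open and was not tested.

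The RiboTag to bulk ratio rose with transcript length (Spearman rho of 0.49 over 845 genes), from a median log2 ratio of -2.71 in the 169 shortest genes to -0.04 in the 169 longest. The median of neuron genes was -1.52 (95% interval -2.77 to 0.27, 19 genes), which cannot tell whether neuron RNA was enriched, since the 0 of this ratio depends on scaling. In limma the list medians were -4.89 for fibroblast and vascular genes, -3.85 for Schwann and satellite glia genes and 0.43 for immune cell genes (4, 2 and 4 genes), none matched for length. Among these neuron genes rho was 0.55 (permutation p = 0.0177), which a loss of short transcripts could produce. A biological cause remains open.

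For the CSDE1 lists, the smallest false discovery rate, that of Ebf1, was 0.159, which chance among 59188 transcripts could give. The number with p under 0.01 does not settle it: 592 were expected by chance (upper limit 640), 530 are listed, and by rank up to 694 can have had such a p. The 592 and 640 assume evenly spread p-values and enough reads for each of the 59188 transcripts to reach such a p. That was not tested, at a depth of 126600 to 363700 reads per library, so no conclusion is drawn from these numbers. Chemoreceptor transcripts such as Olfr1310 made up 7.55% of the lists (40 transcripts, 95% interval 5.45% to 10.1%) against 6.25% of annotated protein-coding transcripts. Lists that follow the annotation could give this share, but 1 gene class does not settle it for the lists. Binding of single transcripts by CSDE1 remains open, and no biological explanation was tested.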

How the results depend on the processing

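Calls of single genes were often lost. For Atf3, Gadd45a, Adcyap1 and Gal in bulk, 26 alternative values stayed past the threshold and 26 did not, and for the 6 genes called in RiboTag, Sox11 and Map1b among them, 62 did and 40 did not. For 16 genes named in RiboTag against bulk, 263 did, 24 did not and 1 reversed, Kcnh5, at -1.33 in injured DRG. Of values of 38 gene results that had not passed, 495 stayed so and 57 passed. Unless stated, the cause was not tested. Quantile scaling gave 17 genes in RiboTag, 328 in RiboTag against bulk and 313 CSDE1 transcripts. A pseudocount of 0.1 gave 2, 69 and 72, and one of 0.5 gave 3 in RiboTag. An adjusted p under 0.1 gave 8 genes in bulk and 55 CSDE1 transcripts. Leaving out 1 replicate gave 0 to 1 gene in bulk, 1 to 107 in RiboTag, 0 to 1 in the difference of effects, 37 to 289 in RiboTag against bulk and 123 to 154 CSDE1 transcripts. All adult libraries in 1 fit gave 0 genes in bulk and 53 in RiboTag, and RiboTag against bulk in injured DRG gave 413. Estimated correlation left 0 lists in bulk and 0 in RiboTag, and fry gave 6 in bulk, 0 in RiboTag and 9 in RiboTag against bulk. The bulk lists hold genes that the authors selected on bulk p in the same libraries, so that count of 6 is not independent evidence. The rank correlation of injury effects was 0.52 among genes with at least 50 CPM and 0.21 to 0.27 without 1 replicate. The rest were added after the data were seen. Counting bulk uninjured replicates 1 and 2 as 2 samples gave 12 genes in bulk, 2 in the difference of effects and 330 in RiboTag against bulk, and with a replicate block 51 in bulk. Adjustment over the table alone, where fewer genes are adjusted for, gave 102 genes in bulk, 2 in the difference of effects and 333 CSDE1 transcripts, and over all features tested by the authors 2 in RiboTag. The edgeR test on reads gave 20 genes in RiboTag, 34 with a minimum count of 1 and 30 without the 2 shallowest libraries, where limma gave 0. A separate spread for each kind of library gave 298 in RiboTag against bulk. Not run were alternatives that need read counts in all libraries (TMM and RLE factors, library totals, another filterByExpr minimum, DESeq2, voom) and all on CSDE1 against IgG. Depth was low in RiboTag, where the 2 shallowest libraries, uninjured replicate 2 and injured replicate 1, held 51700 and 30100 reads. Pooled depth was also higher in uninjured RiboTag libraries (496700 reads) than in injured ones (222100 reads). How depth affected the number of genes called was not tested.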

Other observations

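Ion channel and pan-neuronal genes had too few measured members for a list test, and none passed the threshold in bulk. The potassium channel genes Kcnab1 and Kcnb2 had 60, 54 and 69 and 56, 63 and 37 CPM in uninjured bulk DRG, and 36, 40 and 52 and 29, 38 and 31 CPM after injury. With Scn11a, 3 of 3 measured channel genes were lower, 1 when adjusted over the list alone. Of pan-neuronal genes 3 of 3 were higher, Syt4 (124 ± 1.41 to 201 ± 9.29 CPM, SD, n = 2 and 3), Stmn2 and Slc17a6, 2 when adjusted over the list alone. Slc17a6 had 73, 78 and 98 CPM in uninjured and 130, 117 and 113 CPM in injured bulk libraries, but 225, 97 and 191 against 100, 18 and 38 CPM in RiboTag RNA.

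Small lists gave single values. Of immediate-early genes 3 of 3 were higher in bulk (Dusp1 at 31, 26 and 16 against 42, 37 and 38 CPM), 0 when adjusted over the list alone. RNA-binding protein genes were higher in 2 of 2 cases (Hnrnpa1 at 111, 111 and 109 against 156, 145 and 126 CPM) and cell cycle genes in 2 of 2 (Hmgb2 at 0, 4 and 6 against 16, 10 and 12 CPM). Of Schwann and satellite glia genes, Fabp7 had 585, 590 and 772 against 545, 455 and 273 CPM and Glul 111, 140 and 146 against 136, 247 and 194 CPM. The ribosomal protein gene Rpl37 had 287, 280 and 261 against 263, 217 and 237 CPM.

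Transcripts with lower values under 5'UTRm had a median length of 2169 nt and those with higher values 1433 nt, with a median GC content of 48.5% and 52.0%. Of the genes in the CSDE1 lists, 16 lower and 21 higher ones were also in the adult table, 1 and 3 of them with a false discovery rate under 0.05 in bulk. Tac1 had 8 and 0 CPM in control IPs and 52 and 10 CPM with 5'UTRm, and Nppb, a natriuretic peptide of pruriceptive neurons, 0 and 3 against 22 and 21 CPM. No test of these overlaps was run.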
